A study of Mus musculus with 18 samples.

How the data were processed

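RNA from 18 samples of sorted mouse CD4 T cells was measured on Affymetrix mouse GeneChip arrays that carry 45101 probe sets. Per the labels, the cells were freshly isolated from spleen and lymph nodes of B6;129 mice, RNA was taken up in Isogen and cleaned on RNeasy columns, and it was labelled with the GeneChip two-cycle kit. The 7 groups are conventional T cells (Tconv, 2 arrays), wild-type Treg cells with the GFP reporter (WT GFP, 2 arrays) and with the hCD2 reporter (WT hCD2, 2 arrays, numbered 3 and 4), wild-type GFP Treg cells of mice that also carry A384T Treg cells (3 arrays), and Treg cells expressing Foxp3 A384T, I363V or R397W (3 arrays each). The number of arrays limits the precision of every value. The labels speak of duplicates and triplicates and do not say that each array is a separate animal, so every p measures the spread between these samples.

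The authors deposited log2 values made by RMA, per the labels, which give neither its software nor its version. The log base was taken from the convention of RMA. The deposited values of each probe set are shifted so that the 2 Tconv arrays average 0: their sum was at most 1.0e-06 at every probe set. Differences between groups are unaffected by this shift, but the level of each probe set is lost. The values ran from -5.80 to 7.59, and the medians of the arrays from -0.06 to 0.016. No array was left out and no further normalization was applied.

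The choices of groups, comparisons, tests, gene lists, named genes and most alternatives were made before the data were examined. Some of them assumed expression levels. A filter on dim probe sets, the choice of the brightest probe set per gene, a second quantile normalization and a variance prior that follows the level could not be applied to centred values. In their place no filter was used, and each gene was represented by the probe set with the largest variance over the 18 arrays among those assigned to exactly 1 gene. The chip annotation assigned 34945 probe sets to 1 gene, 932 to several and 9211 to none, and 13 others were set aside. Control probe sets were not used. The 34945 probe sets gave 18193 genes, of which 9010 had several probe sets. Background correction and scan batches were not analysed here, since scanner files were not used.

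Group means of all 18 arrays were fitted together with limma 3.58.1 in R 4.3.3, which leaves 11 residual degrees of freedom, and the variances were moderated by eBayes (3.3 prior degrees of freedom). Each gene had a two-sided moderated test, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 18193 genes. Changes are log2 differences ± SE from this fit. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. Tested on simulated data with 200 changed genes among 18193 in 5 draws, the A384T against WT hCD2 design recovered 22.0%, 72.4%, 96.8% and 99.2% of genes changed by 0.5, 1, 2 and 3 on the log2 scale, with 4.7% false calls. The comparison within A384T mice recovered 25.6%, 78.4%, 98.8% and 99.2%, with 4.2% false calls, and the same comparison with mice as blocks recovered 36.8%, 79.2%, 98.0% and 100.0%, with 1.0% false calls. The simulations without blocks drew every array independently. Some real arrays deviate together, as given below, so these rates may not hold for them.

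The mutants were each compared with WT hCD2, which carries the same reporter, and with each other. A384T cells were also compared with the wild-type cells of the same mice, and this difference was compared with the reporter difference in wild-type mice. The last comparison is an interaction. For A384T and wild-type GFP cells of A384T mice, arrays with the same number deviated together from their group means: the correlations across genes were 0.69, 0.65 and 0.58 for equal numbers and -0.45 to -0.16 for unequal ones. The numbers therefore pair these samples, from the data and not from a label, and a limma fit of these groups alone with the number as a block is given beside the fit without it. Such pairs are called mice below, although no label says that arrays of equal number come from the same mouse.

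Of the gene lists, 16 describe programmes: Treg core genes higher and lower in Treg cells, effector and tissue Treg, naive T cell, T helper cytokines, Th1, Th2, Th17, Tfh, chemokine and homing receptors, AP-1 family, TCR and NF-kB early response, IL-2 and STAT5 signalling, cell cycle, type I interferon response and heat shock. A further 7 hold markers of B cells, myeloid cells, dendritic cells, CD8 T and NK cells, erythroid cells, stromal and endothelial cells, and T cell identity. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted within a comparison over the 16 programme lists or the 7 marker lists, and again with an estimated correlation. On simulated data with genes drawn independently, camera gave an unadjusted p under 0.05 for 20 of 20 shifted lists and 7 of 180 unshifted ones. That simulation cannot measure false calls of lists whose genes vary together. Some list members were not analysed here, among them Lrrc32, Tigit, Tcf7, Il1rl1, Areg and Lck. Some lists share members: Icos, Itgae, Ebi3, Fgl2 and Tnfrsf9 stand in both the Treg core and the effector list, and Cxcr3, Tbx21, Ccr8 and Gata3 also stand in helper programmes.

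Treg signature sets were the genes called between WT GFP and Tconv. They were tested with camera in each mutant against WT hCD2, so that both contrasts shared no array, and adjusted over the 12 tests of these sets in the mutants and between them. Overlaps of mutant effects were set beside 100 simulations of unchanged groups against the same controls, beside the overlap of independent lists, and beside the value with split controls. Named genes are Foxp3 and Batf, the 8 largest changes each way among called genes without overlapping arrays (4 each way for the comparisons between mutants, and for the reporter-adjusted comparison 4 each way among all called genes, overlapping or not, which departs from the planned rule), and up to 4 members of each list described, those with the lowest adjusted p. Clones, predicted genes and receptor segments were passed over. As a check of sex, the 3 Y-linked genes measured ranged over at most 0.62 across the arrays and Xist over 1.66, and no array stood apart. The alternatives were the mean of a gene's probe sets, median centring, a fit of only the groups compared, robust eBayes without trend, array weights, a 2-fold minimum, the genes with the larger variance, other wild-type controls, blocks, and leaving out each array.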

Results

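Foxp3 is the X-linked transcription factor that defines regulatory T (Treg) cells, and in heterozygous female mice each Treg cell uses either the allele tagged with hCD2 or the wild-type allele tagged with GFP. Sorting on these surface and fluorescent reporters gave Treg cells expressing Foxp3 A384T, I363V or R397W (3 arrays each) and wild-type hCD2 Treg cells (2 arrays). Wild-type GFP Treg cells came from wild-type mice (2 arrays) and from A384T mice (3 arrays), and conventional T cells (Tconv) negative for both reporters were also measured (2 arrays). Expression of 18193 genes was compared on the log2 scale. Array values are given relative to the mean of the Tconv arrays. All adjusted p are from limma, and those of gene lists are from its camera test.

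The first comparison asked which genes set wild-type Treg cells apart from Tconv cells (2 GFP and 2 hCD2 arrays against 2). The fit took these arrays as independent. However, WT GFP 1 and WT hCD2 3 deviated together (0.77 across genes), as did WT GFP and Tconv arrays of equal number (0.71). The SE and p of this comparison ignore that structure. In groups of 2 arrays the deviations mirror each other, so the other pair of arrays adds no further evidence. Foxp3 was 150-fold higher in Treg cells (log2 change 7.23 ± 0.18, adjusted p = 1.09e-11), and Il2ra, the alpha chain of the IL-2 receptor, was 40.5-fold higher (5.34 ± 0.17). The next largest increases were in the TGF-beta activating integrin Itgb8 (4.92 ± 0.31), the transcription factors Ikzf2 (4.82 ± 0.15) and Plagl1 (4.78 ± 0.38). They were followed by the adhesion receptor Itgae (4.59 ± 0.22), the phosphatase Dusp4 (4.57 ± 0.30) and the cytokine signalling inhibitor Socs2 (4.54 ± 0.18). The lectin receptor Klrd1 fell most (-4.91 ± 0.31), followed by the lipid transporter Atp8b4 (-4.71 ± 0.20), the cytoskeletal adaptor Pdlim4 (-4.44 ± 0.26) and App (-4.30 ± 0.31). Lypd6b (-4.01 ± 0.22), Hs3st3b1 (-3.59 ± 0.21), the phosphodiesterase Pde3b (-3.50 ± 0.27) and Arhgap29 (-3.20 ± 0.27) were also lower. Batf, an AP-1 factor of effector Treg cells, was 1.14 ± 0.25 higher (adjusted p = 0.0128).

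All 26 measured Treg core genes of the higher list rose, also when adjusted over the list alone (median 3.31, adjusted p = 9.32e-73). Of 14 core genes lower in Treg cells, 6 fell, among them Tgfbr3 (-2.34 ± 0.15), Dapl1 (-3.02 ± 0.28) and Il2 (-0.85 ± 0.10), while Id3 rose (1.43 ± 0.29). Adjusted over the list alone, 9 fell and 2 rose (median -0.90, adjusted p = 4.82e-07). In the effector and tissue Treg list 19 of 27 genes rose and 8 were not called, 23 rose adjusted over the list alone, and the list was higher (median 1.77, adjusted p = 1.73e-25). Of 19 chemokine and homing receptors 8 rose, including Ccr6 (2.59 ± 0.21), Gpr15 (3.26 ± 0.34) and Ccr8 (2.02 ± 0.33), and 9 rose adjusted over the list alone (adjusted p = 8.96e-10). The Tfh list (8 genes, adjusted p = 0.000418) had 5 higher genes, among them Pdcd1 (2.48 ± 0.23), Icos (1.42 ± 0.29) and Cxcr5 (1.07 ± 0.23), and Il21 lower (-2.17 ± 0.25), with the same counts adjusted over the list alone. In IL-2 and STAT5 signalling 5 of 12 genes rose, such as Cish (2.58 ± 0.19) and Il2rb (3.59 ± 0.45), and 7 rose adjusted over the list alone (adjusted p = 7.3e-15). These lists were also called with an estimated correlation (adjusted p = 2.01e-05 to 0.0236).

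Other lists were higher only with the preset correlation. In the Th17 list Ccr6 and Ahr (2.63 ± 0.34) were higher among 5 genes (adjusted p = 0.00347; adjusted p = 0.148 with an estimated correlation). In TCR and NF-kB early response 1 of 16 genes was higher (adjusted p = 0.000418; 0.211 with an estimated correlation). The cell cycle list had Tk1 (1.64 ± 0.34) higher among 23 genes (median 0.76, adjusted p = 1.4e-05; 0.311 with an estimated correlation). Adjusted over the list alone, 3 genes were higher and 1 lower in the Th17 list, and 1 was higher in each of the other lists. The remaining lists were not called: naive T cell (1 higher, 2 lower of 13, adjusted p = 0.0608), T helper cytokines (1 higher, 2 lower of 13, adjusted p = 0.393), Th1 (0 of 7 called, adjusted p = 0.359) and Th2 (3 higher of 7, adjusted p = 0.0538). Neither were AP-1 (2 higher of 10, adjusted p = 0.157), type I interferon response (1 higher, 1 lower of 13, adjusted p = 0.139) and heat shock (1 higher of 8, adjusted p = 0.0995). In total, limma called 694 genes higher and 369 lower in Treg cells. Without Tconv array 1 it called 409 higher, and without Tconv array 2 it called 408 higher and 187 lower, while the 16 genes named as largest changes stayed called with each array left out.

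**Figure D1:**
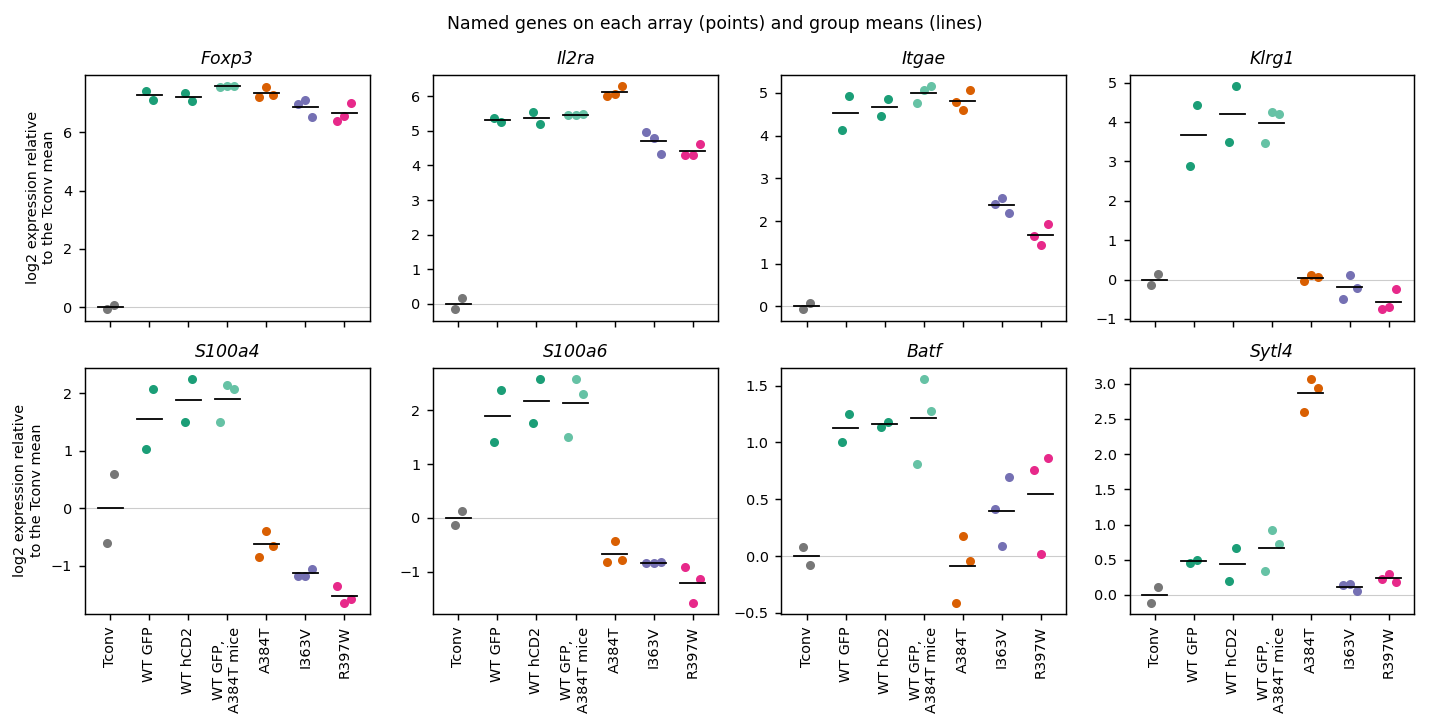
Log2 values of named genes on each of the 18 arrays, relative to the mean of the Tconv arrays; points are arrays and bars are group means. Klrg1 lay between 2.89 and 4.92 on the wild-type Treg arrays and between -0.05 and 0.11 on the A384T arrays.

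The next comparison asked what the A384T substitution changes in Treg cells with the same reporter (3 A384T arrays against 2 WT hCD2 arrays). The killer cell lectin receptor Klrg1, a marker of effector Treg cells, fell 17.9-fold (-4.17 ± 0.42, adjusted p = 0.000903): its mean was 4.21 ± 1.01 (SD, n = 2) in WT hCD2 and 0.04 ± 0.08 (SD, n = 3) in A384T cells. The calcium-binding proteins S100a6 (-2.84 ± 0.33) and S100a4 (-2.50 ± 0.35) fell as well, together with the myosin Myo1f (-2.34 ± 0.35), Myadm (-2.16 ± 0.32), the semaphorin Sema6d (-2.02 ± 0.33), the choline dehydrogenase Chdh (-1.97 ± 0.32) and Ttc39c (-1.91 ± 0.31). Sytl4, a granule-docking protein, rose 5.40-fold (2.43 ± 0.18, adjusted p = 2.1e-05). The calcium channel Ryr2 (1.95 ± 0.23), the actin regulator Enah (1.71 ± 0.19), the tubulins Tubb2b (1.66 ± 0.23) and Tubb2a (1.59 ± 0.25), Sp6 (1.33 ± 0.21), Socs2 (1.24 ± 0.19) and Camk2n1 (1.20 ± 0.22) also rose. Foxp3 RNA did not differ detectably (0.15 ± 0.19, adjusted p = 0.896), and the change of Batf did not pass (-1.25 ± 0.27, adjusted p = 0.0807).

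In the effector and tissue Treg list Klrg1, Lgals1 (-1.48 ± 0.27), S100a4 and S100a6 fell and 23 of 27 genes were not called; 7 fell adjusted over the list alone (median -0.42, adjusted p = 7.86e-09; adjusted p = 0.249 with an estimated correlation). Myeloid markers stood lower as well without a called gene (2 lower adjusted over the list alone, median -0.68, adjusted p = 0.00241; 0.581 with an estimated correlation). The higher Treg core list had 1 gene higher (Socs2) and 1 lower (Nrn1, -1.71 ± 0.19) among 26, 2 higher and 5 lower adjusted over the list alone, and was not called (adjusted p = 0.0732). Tgfbr3 rose (0.81 ± 0.15) among the 14 core genes lower in Treg cells, 2 rose adjusted over the list alone (median 0.23, adjusted p = 0.0195; 0.196 with an estimated correlation; median 0.09 without WT hCD2 array 4). IL-2 and STAT5 signalling was higher with Socs2 called among 12 genes (2 adjusted over the list alone, median 0.26, adjusted p = 0.000288; 0.399 with an estimated correlation); Il2ra itself did not pass (0.75 ± 0.18, adjusted p = 0.147). The cell cycle list was lower with 0 of 23 genes called, also adjusted over the list alone (median -0.81, adjusted p = 7.83e-06; 0.439 with an estimated correlation). Its medians were 0.42 and 1.17 on WT hCD2 arrays 3 and 4 and -0.25, 0.52 and -0.19 on the A384T arrays, and without WT hCD2 array 4 its change shrank to -0.32 (adjusted p = 0.0399). Without the same array the IL-2 and STAT5 call was lost (median -0.06, adjusted p = 0.177), and without A384T array 1 that of the lower core genes (adjusted p = 0.0978). Against WT hCD2, limma called 25 genes higher and 26 lower in A384T cells. Without WT hCD2 array 3 it called 13 and 15, and without array 4 it called 9 and 4. Without A384T array 1 it called 21 and 10, without array 2 it called 14 and 14, and without array 3 it called 12 and 9. Sytl4, Ryr2, Enah, Klrg1 and S100a6 were the 5 of the 16 largest changes called in every such fit.

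For I363V (3 arrays against the 2 WT hCD2 arrays), the largest decreases were Klrg1 (-4.41 ± 0.42, 21.2-fold), the immunosuppressive protein Fgl2 (-3.31 ± 0.47), S100a4 (-3.00 ± 0.35) and S100a6 (-3.00 ± 0.33). Next came the transketolase-like Tktl1 (-2.77 ± 0.38), the enkephalin precursor Penk (-2.70 ± 0.31), the homing receptor Gpr15 (-2.59 ± 0.35) and granzyme B (Gzmb, -2.45 ± 0.46). The largest increases were the desmosome protein Dsp (2.38 ± 0.33), Lypd6b (2.32 ± 0.24, adjusted p = 0.000288), Pde3b (1.99 ± 0.28) and the guanylate cyclase subunit Gucy1b1 (1.95 ± 0.36). Ggt5 (1.89 ± 0.21), the neuropeptide receptor Vipr1 (1.81 ± 0.14), Tdrp (1.80 ± 0.13) and Hexim1 (1.73 ± 0.36) also rose. Pde3b and Lypd6b are genes that were lower in Treg than in Tconv cells. Foxp3 (-0.34 ± 0.19, adjusted p = 0.696) and Batf (-0.76 ± 0.27, adjusted p = 0.317) did not pass.

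In I363V cells 8 of 26 higher Treg core genes fell, among them Itgae (-2.28 ± 0.23), Penk, the ectonucleotidase Entpd1 (-1.34 ± 0.16) and Cd83 (-1.75 ± 0.22), and 21 fell adjusted over the list alone (median -1.08, adjusted p = 1.62e-31). Pde3b and Tgfbr3 (0.95 ± 0.15) rose among the 14 core genes lower in Treg cells, 5 adjusted over the list alone (median 0.47, adjusted p = 3.23e-06; median 0.19 without WT hCD2 array 4). The effector and tissue list had 13 of 27 genes lower, 22 adjusted over the list alone (median -1.42, adjusted p = 4.25e-35). Among 19 chemokine and homing receptors 7 fell, including Cxcr5 (-1.68 ± 0.24) and Cxcr3 (-1.89 ± 0.30), 11 adjusted over the list alone (median -0.69, adjusted p = 5.11e-13). In the Tfh list Cxcr5, Pdcd1 (-1.26 ± 0.25) and Tox2 (-1.43 ± 0.30) fell among 8 genes, and 5 fell and 1 rose adjusted over the list alone (adjusted p = 3.97e-05). These 5 lists kept their calls with an estimated correlation (adjusted p = 0.00114 to 0.0107).

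Further I363V list calls were lost with an estimated correlation. Th1 was lower with Cxcr3 called among 7 genes (3 adjusted over the list alone, adjusted p = 0.000208; 0.0864 with an estimated correlation). Th17 was lower with Ccr6 (-1.08 ± 0.22) called among 5 (2 adjusted over the list alone, adjusted p = 0.0283; 0.263 with an estimated correlation). With no gene called, Th2 (adjusted p = 0.00982; 0.17 with an estimated correlation), IL-2 and STAT5 signalling (adjusted p = 0.0283; 0.423 with an estimated correlation) and cell cycle (median -0.58, adjusted p = 0.00465; 0.423 with an estimated correlation) were lower. Likewise with no gene called, naive T cell (adjusted p = 0.00966; 0.16 with an estimated correlation) and TCR and NF-kB early response (adjusted p = 0.00452; 0.263 with an estimated correlation) were higher. So were AP-1 (median 0.72, adjusted p = 0.0379; 0.263 with an estimated correlation) and type I interferon response (adjusted p = 0.035; 0.423 with an estimated correlation). The AP-1 gene Fosb was at 6.01 on I363V array 2 and at 2.70 and 1.76 on the other I363V arrays. TCR and NF-kB medians were 0.64, 1.42 and 0.46 on the I363V arrays and 0.55 and 0.54 on the WT hCD2 arrays, and without I363V array 2 the calls of this list and of AP-1 were lost (adjusted p = 0.786 for each). Cell cycle medians were 0.33, 0.64 and -0.06 on the I363V arrays and 0.42 and 1.17 on WT hCD2 arrays 3 and 4. Without WT hCD2 array 4 the cell cycle change was -0.11 (adjusted p = 0.545), and the naive T cell (adjusted p = 0.266), Th17 (adjusted p = 0.294) and interferon calls (adjusted p = 0.481) were lost as well. The Th2 call was lost without WT hCD2 array 3 (adjusted p = 0.0644). Cd22 fell among 9 B cell markers (-1.03 ± 0.23; list adjusted p = 0.0142, 0.634 with an estimated correlation). In I363V cells limma called 42 genes higher and 124 lower. Without WT hCD2 array 3 it called 24 and 72, without array 4 it called 6 and 22, without I363V array 3 it called 21 and 56, and without I363V array 1 it called 70 lower. In every such fit 8 of the 16 largest changes were called (Lypd6b, Ggt5, Vipr1, Tdrp, Klrg1, S100a4, S100a6 and Penk). Without WT hCD2 array 3 the IL-2 and STAT5 list turned direction (median 0.04, adjusted p = 0.99).

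R397W cells (3 arrays against the 2 WT hCD2 arrays) had the most called genes of the mutants in the fit of all arrays, but not in fits of only the groups compared (3 higher and 29 lower, against 8 and 26 for I363V). Klrg1 fell 27.3-fold (-4.77 ± 0.42). Over the arrays of all mutants it lay between -0.76 and 0.12, near the Tconv arrays (-0.13 and 0.13). Whether this is background cannot be told from centred values, so the folds of Klrg1 do not rank the mutants. Lysozyme 1 (Lyz1, -4.41 ± 0.38), Fgl2 (-3.71 ± 0.47), S100a4 (-3.40 ± 0.35), S100a6 (-3.38 ± 0.33), Tktl1 (-3.18 ± 0.38), Gpr15 (-3.12 ± 0.35) and Itgae (-2.99 ± 0.23, adjusted p = 1.38e-05) were the next largest decreases. Increases were led by Lypd6b (2.67 ± 0.24), Ggt5 (2.40 ± 0.21), Pde3b (2.17 ± 0.28), Dsp (1.99 ± 0.33), Vipr1 (1.97 ± 0.14), the IL-36 receptor Il1rl2 (1.91 ± 0.22), Tdrp (1.89 ± 0.13) and the cytokine Il21 (1.79 ± 0.26). Foxp3 (-0.55 ± 0.19, adjusted p = 0.217) and Batf (-0.61 ± 0.27, adjusted p = 0.373) did not pass.

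Of the 26 higher Treg core genes 15 fell in R397W cells, with Itgae, Entpd1 (-1.82 ± 0.16), the cytokine subunit Ebi3 (-2.67 ± 0.29) and Cd83 (-1.91 ± 0.22) among them, and 25 fell adjusted over the list alone (median -1.07, adjusted p = 3.28e-34). Tgfbr3 (1.51 ± 0.15), Pde3b, Il2 (0.59 ± 0.10), Themis (1.31 ± 0.26) and Dapl1 (1.20 ± 0.29) rose among the 14 lower core genes, 6 adjusted over the list alone (median 0.38, adjusted p = 5e-06; median 0.15 without WT hCD2 array 4). The effector and tissue list had 18 of 27 genes lower, 25 adjusted over the list alone (median -1.69, adjusted p = 2.83e-39). Among 19 chemokine and homing receptors 8 fell, including Cxcr3 (-2.32 ± 0.30) and the integrin Itgb1 (-2.68 ± 0.35), 10 adjusted over the list alone (median -0.89, adjusted p = 1.9e-13). In the Tfh list Cxcr5 (-1.70 ± 0.24), Tox2 (-1.81 ± 0.30) and Icos (-1.62 ± 0.31) fell and Il21 rose, 5 and 1 adjusted over the list alone (adjusted p = 7.2e-05). Cxcr3, Tbx21 (-1.75 ± 0.27) and Il18rap (-1.83 ± 0.37) fell in the Th1 list of 7 genes, 4 adjusted over the list alone (median -1.39, adjusted p = 1.66e-05). With an estimated correlation these lists were called too (adjusted p = 0.000784 to 0.0461).

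The remaining R397W calls were lost with an estimated correlation. Il2ra (-0.97 ± 0.18), Pim1 (-1.10 ± 0.24), Socs2 (-0.78 ± 0.19) and Il2rb (-1.93 ± 0.47) fell among 12 IL-2 and STAT5 genes, 5 adjusted over the list alone (adjusted p = 1.53e-05; 0.133 with an estimated correlation). Ccr8 (-2.03 ± 0.34) and Gata3 (-1.18 ± 0.26) fell among 7 Th2 genes, 3 adjusted over the list alone (adjusted p = 0.00148; 0.0912 with an estimated correlation). The AP-1 list was lower with 0 of 10 genes called (median -0.46, adjusted p = 0.00756; 0.144 with an estimated correlation), and without R397W array 1 its median was -0.29 (adjusted p = 0.0467). Jun did not pass (-3.07 ± 0.94, adjusted p = 0.135) and was at -3.68 and -3.22 on R397W arrays 1 and 3 and at 0.88 on array 2. With no gene called the cell cycle list was lower (adjusted p = 0.0281; 0.537 with an estimated correlation) and the interferon list higher (adjusted p = 0.0392; 0.436 with an estimated correlation). The cell cycle medians were 0.81, 0.20 and 0.07 on the R397W arrays and 0.42 and 1.17 on WT hCD2 arrays 3 and 4, and without WT hCD2 array 4 the change was -0.07 (adjusted p = 0.952) and the interferon call was lost (adjusted p = 0.491). The naive T cell list was not called (adjusted p = 0.185), and its median (-0.03) differed in sign from its mean (0.18) and its test. Among 10 myeloid markers Lyz2 fell (-2.66 ± 0.35), 6 fell adjusted over the list alone (median -0.87, adjusted p = 3.49e-06; 0.151 with an estimated correlation); Lyz1 lay between -3.88 and -3.09 on the R397W arrays. In R397W cells limma called 130 genes higher and 282 lower. Without WT hCD2 array 3 it called 45 and 140, without array 4 it called 45 and 118, and without R397W array 1 it called 81 higher. Of the 16 largest changes only Dsp was not called in every such fit.

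**Figure D2:**
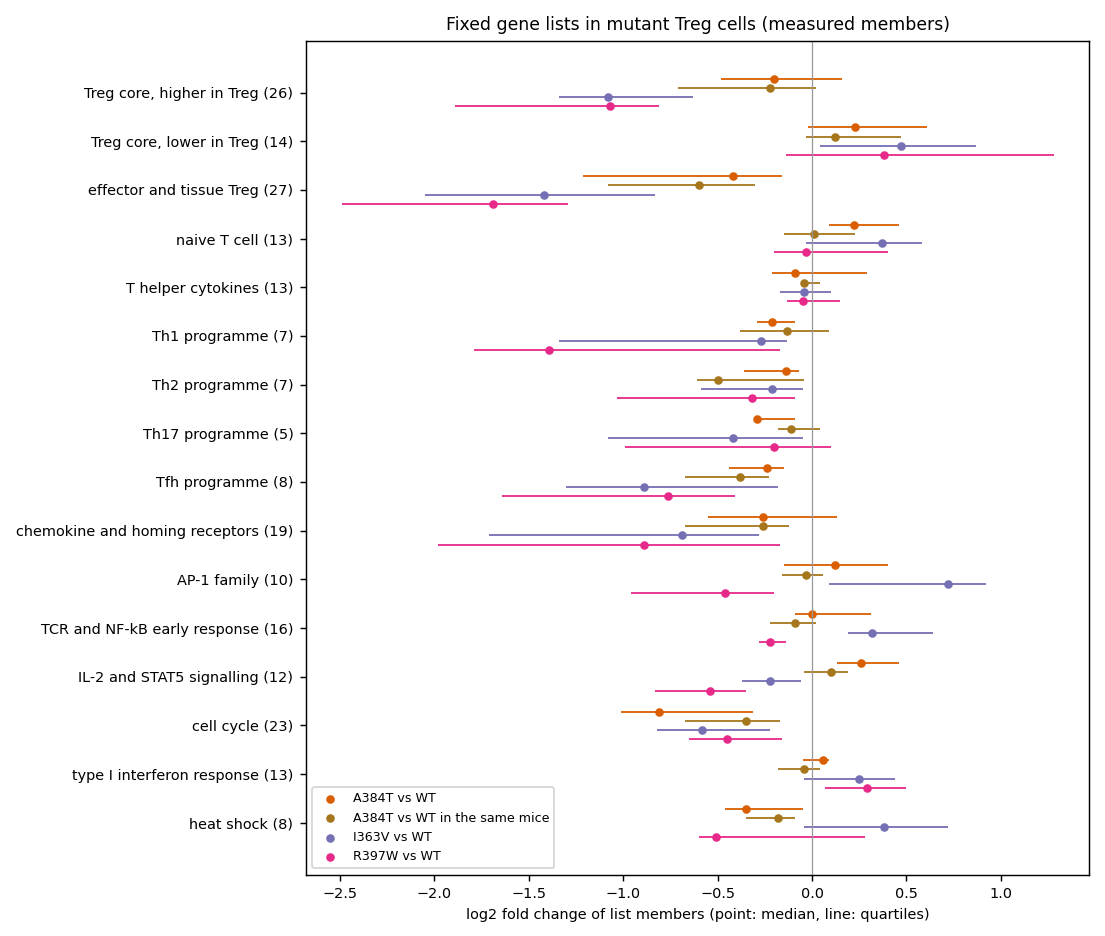
Median log2 change of each programme list in the mutants, with the quartiles of its genes as bars. The effector and tissue Treg list has medians of -0.42 in A384T, -1.42 in I363V and -1.69 in R397W cells, each against WT hCD2.

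A384T cells were also compared with wild-type GFP Treg cells of the same mice (3 arrays each), a comparison that shares the tissue environment but not the reporter. Klrg1 fell 15.3-fold (-3.93 ± 0.38), and S100a6 (-2.79 ± 0.30), S100a4 (-2.53 ± 0.31), Sema6d (-2.40 ± 0.29), Myo1f (-2.35 ± 0.32), Ttc39c (-2.19 ± 0.28), the phosphatase Cdc25b (-2.15 ± 0.30) and the glycosyltransferase Gcnt1 (-2.09 ± 0.28) fell too. Tubb2b rose most (2.64 ± 0.21, adjusted p = 3.4e-05), ahead of Sytl4 (2.21 ± 0.16), Tubb2a (1.84 ± 0.22), Pde3b (1.65 ± 0.25), Stfa3 (1.62 ± 0.28), the gelatinase Mmp9 (1.52 ± 0.28), Enah (1.24 ± 0.17) and Ryr2 (1.21 ± 0.20). The neutrophil genes S100a8 and Ngp stood apart in both populations of mouse 2, at 2.19 and 2.79 in wild-type and 1.69 and 2.25 in A384T cells. Batf was lower (-1.31 ± 0.24, adjusted p = 0.0222), also with mice as blocks (SE 0.08, adjusted p = 5.79e-05), and Foxp3 did not pass (-0.23 ± 0.17).

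In the effector and tissue list Batf, Klrg1, S100a4 and S100a6 fell among 27 genes, 10 adjusted over the list alone (median -0.60, adjusted p = 1.82e-21). With mice as blocks 19 fell, and 20 fell and 1 rose adjusted over the list alone (adjusted p = 1.3e-24). The Tfh list was lower with 0 of 8 genes called, 3 adjusted over the list alone (median -0.38, adjusted p = 5.67e-06), and 4 with blocks. Both calls held with an estimated correlation (adjusted p = 0.02), but with blocks they were lost (adjusted p = 0.316). Socs2 rose and Nrn1 fell among the 26 higher core genes (2 and 6 adjusted over the list alone, median -0.22, adjusted p = 0.000171; 0.153 with an estimated correlation); with blocks Gpr83, Il2ra, Plagl1 and Socs2 rose and 11 fell. Pde3b and Tgfbr3 (0.96 ± 0.14) rose among the 14 lower core genes (adjusted p = 0.0115; 0.0664 with an estimated correlation). Itgb1 (-1.66 ± 0.32) and Gpr15 (-1.65 ± 0.32) fell among 19 chemokine and homing receptors (1 higher and 5 lower adjusted over the list alone, adjusted p = 3.37e-06; 0.0895 with an estimated correlation). The Th2 list was lower with 0 of 7 genes called (2 adjusted over the list alone, adjusted p = 0.00032; 0.0895 with an estimated correlation). IL-2 and STAT5 signalling was higher with Socs2 called (2 adjusted over the list alone, adjusted p = 0.0209; 0.496 with an estimated correlation). The cell cycle list was lower with 0 of 23 genes called (median -0.35, adjusted p = 0.000215; 0.496 with an estimated correlation). With blocks 9 fell, among them Mki67, Top2a, Birc5 and Ube2c (adjusted p = 3.38e-12; 0.32 with an estimated correlation). Without blocks, the cell cycle call was lost when wild-type array 2 was left out (median -0.02, adjusted p = 0.999), that of the lower core genes without A384T array 1 (adjusted p = 0.061) and that of IL-2 and STAT5 without A384T array 3 (adjusted p = 0.0562).

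With mice as blocks 3 further lists were called lower: TCR and NF-kB early response (adjusted p 0.255 without and 0.0216 with blocks), heat shock (0.156 and 0.00768) and myeloid markers (0.486 and 0.00328, 4 of 10 genes lower). With blocks and an estimated correlation, these calls were lost (adjusted p = 0.316 for both programme lists and 0.767 for the myeloid markers). Within A384T mice limma called 31 genes higher and 64 lower without blocks and 330 and 622 with blocks, all 31 and 64 included. Of these, 18 and 46 changed at least 2-fold without blocks and 25 and 72 with blocks, and 687 of the 952 genes called with blocks had no overlap between the arrays of the groups. The fit with blocks held only these arrays and left few residual degrees of freedom per gene. Without blocks, leaving out wild-type array 1 gave 18 higher, array 2 gave 20 and 25, and array 3 gave 15 and 24. Leaving out A384T array 1 gave 26 lower, array 2 gave 16 and 36, and array 3 gave 19 and 34, and without both arrays of mouse 2 the counts were 8 and 10. Named as largest changes, 13 of the 16 genes were called with each single array left out, all but Stfa3, Mmp9 and Ryr2.

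Wild-type GFP Treg cells of A384T mice (3 arrays) were compared with those of wild-type mice (2 arrays) to ask whether mutant Treg cells nearby alter wild-type ones. The limma test called 0 genes, with 473 genes (2.6%) at an unadjusted p under 0.05. Foxp3 (0.30 ± 0.19) and Batf (0.09 ± 0.27) did not pass. Higher as lists, with no gene called, were effector and tissue Treg (median 0.22, adjusted p = 0.00444; 0.566 with an estimated correlation), T helper cytokines (0.16, adjusted p = 0.0136; 0.212 with an estimated correlation) and Th2 (0.19, adjusted p = 0.0136; 0.304 with an estimated correlation). So were chemokine and homing receptors (0.22, adjusted p = 0.0136; 0.566 with an estimated correlation) and Tfh (0.19, adjusted p = 0.0464; 0.304 with an estimated correlation). In each of these lists 0 genes passed adjusted over the list alone, and each call was lost without WT GFP array 1 (adjusted p = 0.165 to 0.868). Between the hCD2 and GFP reporters in wild-type mice (2 arrays each), limma called 0 genes, with 462 (2.5%) at an unadjusted p under 0.05. No list was called, and Foxp3 (-0.07 ± 0.21) and Batf (0.03 ± 0.29) did not pass. This fit was unpaired, although values of WT GFP 1 and WT hCD2 3 correlated at 0.92 across genes. WT GFP 2 and WT hCD2 4 correlated at 0.89, and the crossed arrays at 0.64 and 0.68. The 0 calls therefore do not show that the reporters are alike.

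The A384T change within A384T mice was then taken relative to the reporter difference within wild-type mice, which removes an additive reporter effect. By limma, 5 genes were higher and 4 lower in this interaction, fitted without blocks. Higher were Tubb2b (2.82 ± 0.33, adjusted p = 0.00502), Sytl4 (2.25 ± 0.25, adjusted p = 0.00502), Tubb2a (2.15 ± 0.35), Vipr1 (1.31 ± 0.20) and Tdrp (1.19, named after its value was seen). Lower were Klrg1 (-4.48 ± 0.60, adjusted p = 0.0163), S100a6 (-3.07 ± 0.47), the membrane-anchored neuritin Nrn1 (-1.92 ± 0.27) and the G protein subunit Gna15 (-1.91 ± 0.30). Batf did not pass (-1.34 ± 0.38, adjusted p = 0.652), nor did Foxp3 (-0.15 ± 0.28). The effector and tissue list was lower with Klrg1 and S100a6 called among 27 genes (5 adjusted over the list alone, median -0.70, adjusted p = 7.11e-17). The Tfh list was lower (median -0.59, adjusted p = 0.000444) and the 14 lower core genes were higher (2 adjusted over the list alone, median 0.28, adjusted p = 0.00261; median 0.08 without WT hCD2 array 4). Each of these calls held with an estimated correlation (adjusted p = 0.0302). Calls lost with an estimated correlation were the higher core genes (lower, adjusted p = 0.0112; 0.331 with an estimated correlation), T helper cytokines (lower, 0.0463; 0.158), Th1 (lower, 0.0405; 0.331), Th2 (lower, 0.000444; 0.0875), chemokine and homing receptors (lower, 0.000207; 0.158), IL-2 and STAT5 signalling (higher, 0.0223; 0.452) and cell cycle (lower, 0.00397; 0.503). Counts ranged from 0 to 3 higher and from 0 to 9 lower with single arrays left out, and without both arrays of mouse 2 they were 2 and 0. With the mice of the A384T pairs as blocks, in a fit of all arrays that leaves the wild-type mice unpaired, 3 genes were higher (Tubb2b, Sytl4 and Ddc) and 4 lower (Klrg1, S100a6, Nrn1 and Nav2), of which Ddc and Nav2 are named after their values were seen. In this fit Gna15 (adjusted p = 0.0579), Tdrp (0.0579), Vipr1 (0.0702) and Tubb2a (0.0958) lost their calls, and Batf did not pass (SE 0.32, adjusted p = 0.383). No list call changed with these blocks at the preset correlation, and with an estimated one Th2 was called too (adjusted p = 0.042). Without blocks, the calls of the higher core genes (adjusted p up to 0.138), T helper cytokines (0.343), Th1 (0.542), chemokine and homing receptors (0.0673), IL-2 and STAT5 (0.868) and cell cycle (0.834) were each lost with some single array left out.

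Direct comparisons asked how the mutants differ (3 arrays each). Relative to I363V, A384T cells had higher Matn2 (2.92 ± 0.33), Sytl4 (2.75 ± 0.16), Itgae (2.44 ± 0.20) and Mmp9 (2.25 ± 0.28) and lower Myo6 (-2.72 ± 0.23), Rnf144a (-2.32 ± 0.25), the kinase Sgk1 (-1.82 ± 0.28) and Pxylp1 (-1.70 ± 0.32). Foxp3 (0.48 ± 0.17, adjusted p = 0.345) and Batf (-0.49 ± 0.24, adjusted p = 0.597) did not pass. Of 26 higher core genes 9 were higher, such as Socs2 (1.77 ± 0.17), Il2ra (1.43 ± 0.16) and Entpd1 (0.97 ± 0.14), 22 adjusted over the list alone with 1 lower (median 0.97, adjusted p = 4.06e-26; called with an estimated correlation, 0.00247). Cxcr3 (1.63 ± 0.27), Ebi3 (1.44 ± 0.26), Itgae and Prdm1 (1.04 ± 0.20) were higher among 27 effector and tissue genes, 14 adjusted over the list alone (median 0.74, adjusted p = 1.49e-16). In addition, 3 of 19 chemokine and homing receptors were higher, 9 adjusted over the list alone (adjusted p = 8.98e-10). Both calls held with an estimated correlation (adjusted p = 0.0455). IL-2 and STAT5 signalling was higher with Il2ra and Socs2 called among 12 genes (5 adjusted over the list alone, adjusted p = 5.65e-08; 0.0753 with an estimated correlation). Lost with an estimated correlation were calls of higher Tfh (adjusted p = 0.00889; 0.0753 with an estimated correlation) and Th1 lists (adjusted p = 0.0208; 0.261). Calls of lower lists were lost too, for AP-1 (adjusted p = 0.0321; 0.261), TCR and NF-kB early response (adjusted p = 0.0208; 0.397), heat shock (adjusted p = 0.0229; 0.247) and lower core lists (adjusted p = 0.0208; 0.0674). The AP-1 and the TCR and NF-kB calls were lost without I363V array 2 (adjusted p = 0.831 and 0.858), as were those of heat shock without A384T array 2 (0.0972), Th1 without A384T array 3 (0.0761) and the lower core genes without I363V array 3 (0.0535). Between A384T and I363V, limma called 161 genes higher and 46 lower. Without A384T array 1 it called 21 lower, without A384T array 2 it called 92 higher and 25 lower, and without A384T array 3 it called 29 lower. Without I363V array 1 it called 102 higher, without I363V array 2 it called 29 lower and without I363V array 3 it called 95 higher.

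Against R397W, A384T cells had higher Jun (3.84 ± 0.84, adjusted p = 0.0227), Itgae (3.14 ± 0.20), Matn2 (3.13 ± 0.33) and Lyz1 (2.72 ± 0.34). Lower were Myo6 (-2.86 ± 0.23), Rnf144a (-2.37 ± 0.25), Il1rl2 (-2.16 ± 0.20) and the acetyltransferase Crebbp (-2.05 ± 0.50). Foxp3 RNA was higher in A384T cells (0.70 ± 0.17, adjusted p = 0.0432), and Batf did not pass (-0.64 ± 0.24, adjusted p = 0.195). Of 26 higher core genes 16 were higher, 21 adjusted over the list alone with 1 lower (median 1.20, adjusted p = 1.19e-23). Of 27 effector and tissue genes 12 were higher, 20 adjusted over the list alone with 1 lower (median 1.18, adjusted p = 1.46e-18). IL-2 and STAT5 signalling (5 of 12 higher, 7 adjusted over the list alone, adjusted p = 2.5e-10) and chemokine and homing receptors (7 of 19 higher, 10 adjusted over the list alone, adjusted p = 1.35e-09) were higher. The 14 lower core genes were lower (5 lower, 6 adjusted over the list alone, adjusted p = 0.0156). These calls held with an estimated correlation (adjusted p = 0.00376 to 0.0438). Tbx21 (1.73), Cxcr3 (2.06) and Ifng (2.37 ± 0.45) were higher in the Th1 list of 7 (adjusted p = 0.0138; 0.21 with an estimated correlation). Jun and Junb (1.51 ± 0.36) were higher in the AP-1 list of 10 (adjusted p = 0.0163; 0.21 with an estimated correlation), and 3 genes were higher and Il21 lower in the Tfh list of 8 (adjusted p = 0.0163; 0.108 with an estimated correlation). Calls of AP-1 (adjusted p = 0.0816) and the lower core genes (0.0635) were lost without R397W array 1, and that of Th1 without R397W array 3 (0.0816). Here limma called 404 genes higher and 165 lower. Without A384T array 1 it called 80 lower, without array 2 it called 186 higher and 63 lower, and without array 3 it called 220 and 92.

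I363V and R397W cells differed in fewer genes. Lyz1 (3.70 ± 0.34, adjusted p = 0.000539), Lyz2 (2.36 ± 0.31), Mettl23 (1.91 ± 0.26) and Fam91a1 (1.14 ± 0.19) were higher in I363V cells. Madd (-1.35 ± 0.20), Dido1 (-1.27 ± 0.19), Marveld1 (-1.24 ± 0.21) and the GTPase Gimap7 (-0.96 ± 0.14) were lower. Lyz2 is a myeloid marker, and the medians of these markers were -0.22, -0.07 and -0.39 on the I363V arrays. On the R397W arrays they were -1.25, -0.89 and -1.20. Whether the lysozyme differences come from myeloid cells among the sorted cells was not tested. Of the lists higher in I363V cells with no gene called, AP-1 had 4 genes adjusted over the list alone (median 0.96, adjusted p = 1.68e-06; 0.0701 with an estimated correlation) and TCR and NF-kB early response had 1 (median 0.52, adjusted p = 4.93e-06; 0.295 with an estimated correlation). The TCR and NF-kB medians were 0.64, 1.42 and 0.46 on the I363V and 0.33, 0.25 and 0.41 on the R397W arrays, and without I363V array 2 this change was 0.20 (adjusted p = 0.0189) and that of AP-1 0.13 (adjusted p = 0.00188). Higher too were the higher core genes (median 0.23, adjusted p = 0.00125), effector and tissue Treg (0.38, adjusted p = 0.000249), IL-2 and STAT5 signalling (0.28, adjusted p = 0.00125) and heat shock (0.54, adjusted p = 0.0254). Each of these calls was lost with an estimated correlation (adjusted p = 0.367). Without R397W array 2 the effector (adjusted p = 0.0699), IL-2 and STAT5 (0.348) and higher core calls (0.335) were lost, and without R397W array 3 that of heat shock (0.363). The heat shock gene Hspa1a was at 5.86 on R397W array 2 and at -1.30 and -0.94 on the other R397W arrays. Between I363V and R397W, limma called 4 genes higher and 11 lower. Without I363V array 1 it called 7 higher, without I363V array 2 it called 1 lower and without I363V array 3 it called 10 higher. Without R397W array 1 it called 1 and 0, and without R397W array 2 it called 30 and 27.

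**Figure D3:**
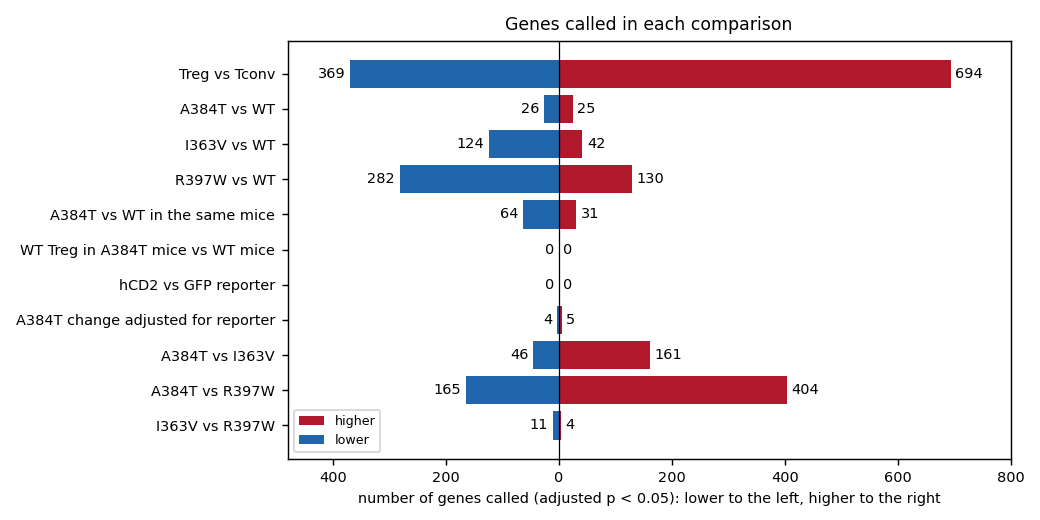
Number of genes called higher and lower by limma in each comparison (adjusted p under 0.05 among 18193 genes). Against WT hCD2 the counts lower were 26 for A384T, 124 for I363V and 282 for R397W.

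Treg signature genes were defined from arrays that do not enter the mutant comparisons: 482 genes higher and 233 lower in WT GFP than in Tconv cells. However, WT GFP 1 and WT hCD2 3 deviated together from their group means (0.77 across genes). With 2 arrays per group, WT GFP 2 and WT hCD2 4 mirror this by construction. The sets are therefore not fully separate from the WT hCD2 controls, which can enlarge set changes and overlaps against them. Comparisons between mutants do not use these controls. In I363V cells the higher set had a median change of -0.49 (adjusted p = 5.28e-57) and the lower set of 0.21 (adjusted p = 3.37e-20), and in R397W cells the medians were -0.65 (adjusted p = 2.39e-69) and 0.27 (adjusted p = 1.34e-26). These calls held with an estimated correlation (adjusted p at most 0.000528). In A384T cells neither set was called (medians -0.01 and -0.00, adjusted p = 0.691 and 0.107), although the lower set was called higher when limited to genes that differ at least 2-fold (median 0.06, adjusted p = 0.00238; 0.138 with an estimated correlation) and passed unadjusted without WT hCD2 array 4. Directly compared with A384T, the higher set was lower in I363V (A384T minus I363V 0.48, adjusted p = 4.51e-62) and in R397W cells (A384T minus R397W 0.61, adjusted p = 6.97e-62), both also with an estimated correlation (adjusted p = 0.000481). It differed between I363V and R397W by 0.14 (adjusted p = 1.53e-07; adjusted p = 0.143 with an estimated correlation). Of the genes that fell in each mutant, 18 of 26 in A384T, 86 of 124 in I363V and 178 of 282 in R397W belonged to the higher set, where independent lists would share 0.7, 3.3 and 7.5. Klrg1, S100a6 and Nrn1 are among the genes lower in all mutants.

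The comparisons with WT hCD2 share their controls, which alone makes the mutants look alike. I363V and R397W had 25 genes higher and 111 lower in both (0.3 and 1.9 for independent lists), with a Pearson correlation of changes across genes of 0.64 and a covariance of 0.067. Unchanged groups simulated against these controls gave 0.60 and 0.030, and an overlap of at most 0 genes. Because the simulated groups held no changed genes, an overlap of 0 was near certain. It sets no baseline for mutants that each have changed genes. A384T shared 4 higher and 17 lower genes with I363V (0.1 and 0.2 for independent lists; correlation 0.58, covariance 0.048, simulated 0.60 and 0.029). It shared 6 and 21 with R397W (0.2 and 0.4; correlation 0.34, covariance 0.032, simulated 0.60 and 0.030), and 6 genes were called in opposite directions in A384T and R397W. With 1 mutant of each pair set against WT GFP instead, I363V and R397W shared 20 and 98 genes (covariance 0.054), A384T and I363V 4 and 15 (0.032), and A384T and R397W 4 and 20 (0.016). Arrays WT GFP 1 and WT hCD2 3 deviated together (0.77 across genes, which are not independent replicates), so these controls are not fully separate. WT GFP 2 and WT hCD2 4 mirror this by construction. Genes lower in all mutants were Klrg1, S100a4, S100a6, Lgals1, Nrn1, Casp4, Cass4, Chdh, Cobll1, Gcnt1, Il17rb, Jdp2, Myadm, Myo1f, Niban1, Sema6d and Ttc39c (17 genes). Ncoa7, Tdrp, Tgfbr3 and Vipr1 were higher in all. The rule for named genes did not name all of these.

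Markers of other cell types were measured in the same comparisons. Dendritic cell markers were lower in wild-type Treg than in Tconv cells, with H2-Aa (-2.43), Itgax (-1.16) and Flt3 (-0.51) called among 7 genes (4 adjusted over the list alone, adjusted p = 0.00196; 0.381 with an estimated correlation). The B cell gene Cd79b rose in Treg cells (2.21 ± 0.26) while its list of 9 was not called (adjusted p = 0.628; its mean of 0.04 had another sign than its median of -0.16). Klrk1 fell (-0.59) among 7 CD8 T and NK cell markers (list adjusted p = 0.548). The erythroid (3 genes, adjusted p = 0.594), stromal and endothelial (6 genes, adjusted p = 0.628), myeloid (10 genes, adjusted p = 0.628) and T cell identity lists (7 genes, adjusted p = 0.0675) were not called there. Between mutants, Nkg7 was higher in A384T than in I363V (2.01) and R397W cells (2.02), Cd22 was higher in A384T than in I363V cells (1.18), and Ms4a1 was lower (-1.59 ± 0.27) and Lyz2 higher (1.34 ± 0.31) in A384T than in R397W cells. Myeloid markers were higher in I363V than in R397W cells with Lyz2 called (adjusted p = 0.0002; 0.334 with an estimated correlation), and B cell markers were lower (median -0.18, adjusted p = 0.0113; 0.377 with an estimated correlation).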

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

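The tests of a reporter difference and of fewer myeloid cells behind the lower A384T genes, and the tests of the cell cycle list, were chosen only after the results were seen.

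The A384T effect within A384T mice differed from the reporter difference within wild-type mice by a limma interaction test in 9 genes, without blocks. Tubb2b (2.82), Sytl4 (2.25), Tubb2a (2.15), Vipr1 (1.31) and Tdrp (1.19) differed upward, and Gna15 (-1.91), Nrn1 (-1.92), S100a6 (-3.07) and Klrg1 (-4.48) downward. With the A384T pairs as blocks, Gna15 (limma adjusted p = 0.0579), Tdrp (0.0579), Vipr1 (0.0702) and Tubb2a (0.0958) lost their calls. A signal also appeared in 10092 probe sets that are not assigned to exactly 1 gene and enter no comparison above, control probe sets left out. Tested alone in the same way, 176 of them differed between Treg and Tconv cells (87 higher, 89 lower), 8 between A384T and WT hCD2 (1 and 7), 14 for I363V (4 and 10), 57 for R397W (36 and 21) and 24 between A384T and wild-type cells of the same mice (8 and 16). No explanation was tested for these probe sets.

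The 64 genes lower in A384T cells than in wild-type cells of the same mice, led by Klrg1, S100a6 and S100a4, had a median change of -1.22 (quartiles -1.65 to -0.95). A reporter or gate difference would give a like fall between WT hCD2 and WT GFP, where the median of these genes was 0.09 (quartiles -0.02 to 0.25), which argues against it as the cause. Fewer myeloid cells in the A384T sort would lower myeloid markers at least as much. Their median was -0.19 (quartiles -0.46 to -0.09), although they stood 0.66 higher in mouse 2 and differed by -0.42 between R397W and A384T cells, so they were free to move. With mice as blocks these markers were called lower at the preset correlation and not with an estimated one, as given above. Some loss of myeloid cells is therefore not excluded. An earlier form of that test, the excess of the 64 genes in mouse 2 (0.12, quartiles 0.00 to 0.22), did not decide, and the deciding form was chosen after that was seen. An effect of A384T on these genes in Treg cells, or on which Treg subsets form, may remain as a hypothesis, and these arrays of sorted populations do not separate the alternatives.

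Genes higher in Treg cells were lower in R397W and I363V cells, which Tconv cells among the sorted cells could produce. Such an admixture lowers all genes with far more RNA in Treg than Tconv cells by about the same amount. Of the 35 genes at least 8-fold higher in Treg cells, 19 (54.3%) lay more than 2 standard errors from their median change in R397W cells (median -1.02, quartiles -1.92 to -0.70; 11 below and 8 above, Foxp3 and Ikzf4 among the latter), and the median would need 50.7% Tconv cells. In I363V cells 22 (62.9%) did (median -0.99, quartiles -1.59 to -0.43; 9 below and 13 above), and the median would need 49.8%. This argues against admixture as the whole cause in both mutants, while a smaller share of Tconv cells and the mutation itself stay open.

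The cell cycle list (Mki67 and Top2a among its members) was lower in A384T cells. Its median change against wild-type cells was -0.17, -0.65 and -0.22 in the array pairs numbered 1, 2 and 3. The highest of these, -0.17, lay between the bounds set for mouse-to-mouse variation. That explanation and an effect of A384T therefore cannot be told apart with 3 pairs, which no label ties to single mice. Between WT hCD2 and WT GFP cells the median was 0.11 (quartiles 0.04 to 0.25 over genes, not samples), not the fall of a reporter difference. Array medians were 0.22 and 1.13 on WT GFP arrays 1 and 2 and 0.42 and 1.17 on WT hCD2 arrays 3 and 4. By these medians neither WT hCD2 array lay below the WT GFP array that its values go with (WT GFP 1 for WT hCD2 3, WT GFP 2 for WT hCD2 4). Without WT GFP array 1 the difference was -0.28. That fit sets WT hCD2 3 against WT GFP 2, which its values do not go with, so it cannot decide. With 2 arrays per group a reporter difference stays open for this list. The estimated correlation within the list also ended its call.

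Regrouping the 6 arrays of a comparison of 3 against 3 gives 10 splits, too few for a share under 0.05, and in each comparison 1 split, the real one, called the most genes. The real split called 95 genes and the highest other 0 for A384T against wild-type cells of the same mice, 207 and 0 for A384T against I363V, 569 and 0 for A384T against R397W, and 15 and 12 for I363V against R397W. In the paired comparison within A384T mice, 4 splits part every pair; with blocks the real one called 952 genes and the highest other 0, and the other splits leave pairs together.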

How the results depend on the processing

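Array weights, robust eBayes without trend, the genes with the larger variance, leaving out the A384T mouse numbered 2 and wild-type cells of A384T mice as split controls were chosen only after the data were seen.

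Arrays with signal lost against background cannot be told here, since the values are centred, and dim genes were kept. Not run, because centred values carry no level, were the filters on dim probe sets at a 40% or 60% rank, the second quantile normalization and eBayes with trend; background correction and scan batch were not run without scanner files. No called named gene changed direction under any alternative run. Median centring changed no count by over 1.5 times, nor did robust eBayes, and the comparisons of wild-type Treg cells between mice and between reporters gave 0 calls under every alternative run. Over the programme lists of Treg against Tconv, the mutants against WT hCD2 and A384T within the same mice, with an estimated correlation 53 list results kept their call status and 27 calls were lost. The cause was not tested for the values that follow, unless fewer arrays or a stricter minimum are its construction.

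Fitting only the groups compared, which leaves fewer residual degrees of freedom, gave 195 genes lower in Treg than Tconv cells, 4 higher and 6 lower for A384T, 8 and 26 for I363V, 3 and 29 for R397W, 102 lower for A384T within the same mice, 3 higher for the reporter-adjusted change, 232 and 66 for A384T against R397W, and 0 lower for I363V against R397W. A 2-fold minimum removed 297 of the 694 genes higher in Treg than Tconv cells, which leaves 4.0e+02 (rounded), and left 137 of the 369 lower. It left 13 higher for A384T, 57 and 160 for R397W, 18 higher within the same mice, 90 and 27 for A384T against I363V, 192 and 52 for A384T against R397W, and 4 lower for I363V against R397W. With both WT reporters as control the counts were 56 and 52 for A384T, 73 and 230 for I363V and 229 and 464 for R397W; with GFP WT as control 22 genes were higher for I363V, and with all 3 WT Treg groups as control 62 were higher and 90 lower for A384T. With GFP WT only, 233 genes were lower in Treg than Tconv cells. Array weights gave 77 and 147 within the same mice, 7 lower for the reporter-adjusted change, 251 and 104 for A384T against I363V, and 7 higher for I363V against R397W. The mean of probe sets gave 10 lower for the reporter-adjusted change and 2 and 1 for I363V against R397W. A like count does not mean that the same genes were called. With the mean of probe sets 18 of 25 genes higher for A384T, 34 of 42 for I363V and 93 of 130 for R397W stayed called. Of the genes lower, 22 of 26, 106 of 124 and 232 of 282 did. Testing only the genes with the larger variance gave 3 and 7 for the reporter-adjusted change and 7 higher for I363V against R397W. Without the A384T mouse numbered 2 there were 12 higher for A384T against WT hCD2, 8 and 10 within the same mice, and 2 and 0 for the reporter-adjusted change. Limiting the Treg signature to a 2-fold set moved the lower set in A384T cells to a median of 0.063, past the threshold of limma's camera (adjusted p = 0.00238; 0.138 with an estimated correlation). With wild-type cells of A384T mice as the control of A384T, 27 genes were lower in both A384T and I363V cells and 44 in both A384T and R397W cells.

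With the replicate number as a block, limma called 330 genes higher and 622 lower for A384T within the same mice, where the numbers pair the samples, and changed no list call other than those given with that comparison. Of the other groups, WT GFP and Tconv arrays of equal number also deviated together (0.71), while the rest share only a number. Block fits gave 23 and 6 for A384T against I363V, 42 and 6 for A384T against R397W, 1 and 0 for I363V against R397W, 0 and 0 for wild-type Treg cells of A384T against wild-type mice, and 2236 and 1111 for WT GFP against Tconv. Each of these fits held only the arrays of the groups compared and left few residual degrees of freedom, fewest where the groups hold 2 arrays. Deviations of equal numbers correlated at -0.32, 0.07 and -0.06 for A384T and I363V, -0.21, -0.17 and -0.09 for A384T and R397W, 0.04, 0.34 and 0.01 for I363V and R397W, -0.05 and -0.04 for WT GFP and wild-type cells of A384T mice, and 0.71 for WT GFP and Tconv, where both pairs mirror each other. Of the mutant pairs, no comparison had every array correlate best with its own number. WT hCD2 arrays are numbered 3 and 4: no paired analysis by number was possible because these share fewer than 2 numbers with the other groups, and a pairing with WT GFP taken from the values alone was not run. The reporter-adjusted change was 3 higher and 4 lower with the number as a block for the A384T pairs only, a fit added after the data were seen.

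Leaving out each array in turn, where a lone remaining array is assumed to vary like the other groups, gave 408 to 604 higher and 187 to 303 lower for Treg against Tconv, 9 to 21 and 4 to 15 for A384T, 6 to 29 and 22 to 100 for I363V, 45 to 164 and 118 to 248 for R397W, and 15 to 23 and 24 to 76 for A384T within the same mice. It gave 0 to 3 and 0 to 9 for the reporter-adjusted change, 92 to 128 and 21 to 33 for A384T against I363V, 186 to 411 and 63 to 236 for A384T against R397W, and 1 to 30 and 0 to 27 for I363V against R397W. The signature's lower set in A384T cells ran from -0.014 to 0.015 and passed camera's threshold, unadjusted, without WT hCD2 array 4. Medians of lists that stayed called shrank from 1.77 to 0.89 for Th17 in Treg against Tconv cells without Tconv array 1 and from -0.89 to -0.55 for Tfh in I363V cells without WT hCD2 array 3. Without R397W array 2 they shrank from -0.54 to -0.26 for IL-2 and STAT5 and from -0.32 to -0.08 for Th2 in R397W cells, and from 0.92 to 0.48 for IL-2 and STAT5 in A384T against R397W cells. Within the same mice chemokine and homing receptors went from -0.26 to -0.14 without A384T array 2. The IL-2 and STAT5 list in I363V cells turned from -0.22 to 0.04 (adjusted p = 0.99) without WT hCD2 replicate 3 and was -0.45 without replicate 4.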

Other observations

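The bound for the hypothesis below was written before its result was seen, and the overlap with genes lower in Treg cells was looked at only after.

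Among the 31 genes higher in A384T cells than in wild-type cells of the same mice, 9 belong to the genes that are higher in WT GFP Treg than in Tconv cells (29.0%, against 2.6% of all genes): Arhgap20, Camk2n1, Ddc, Enah, Ncoa7, Ryr2, Socs2, Sp6 and Xdh. Socs2 encodes an inhibitor of cytokine signalling and Ryr2 a calcium release channel. Another 7 of the 31 are lower in Treg than in Tconv cells (Hs3st3b1, Lypd6b, Pde3b, Tdrp, Tgfbr3, Vipr1 and Xkrx). Of the genes higher in I363V and R397W cells, 1 of 42 and 2 of 130 belong to the Treg-higher set, and 18 and 44 to the Treg-lower set. These sets of genes were named after their values were seen.

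One hypothesis is that A384T may raise further the RNA of genes that Treg cells already express more than Tconv cells. The 9 of 31 genes exceed the 0.8 of independent lists (Fisher's exact p = 7.16e-08, two-sided), but the 7 genes of the Treg-lower set exceed theirs as well (0.4 for independent lists, Fisher's exact p = 1.05e-07). A preference for genes that differ between Treg and Tconv cells in either direction cannot be told apart from the hypothesis, and genes on an array are not independent of each other. The values of independent lists also count all genes, dim ones included.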
